A study of Homo sapiens with 8 samples.

How the data were processed

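The deposited tables held whole-number counts per gene and cell for coding genes, made by the authors, as their labels state, by trimming reads with Trimmomatic 0.36, aligning them to hg38 with HISAT2 2.1.0 and counting them with HTSeq 0.9.1. Cells were picked singly, and a modified Smart-seq2 protocol with 3' mRNA libraries was used. The labels do not state whether the counts are reads or unique molecules, nor whether counting used the strand, so overlapping genes, paralogs and genes with many pseudogenes carry an added uncertainty. Intervals cover only the sampling of cells within a library, and floors only counting error. The 8 tables listed 15041 genes in all and 10829 in common, and a gene missing from a table was taken as 0. Positions and pseudogene names came from GENCODE 29, in which 15031 of the 15041 identifiers were found without their version and 13733 with it.

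A cell was kept when it had at least 1000 detected genes and 5000 counts. Counts of kept cells were summed per library, so the cells with most counts weigh most: the 10 largest cells held 39.3% to 54.9% of a library's counts, and 65 kept cells lay above 2 times their library's median. Genes were filtered with filterByExpr, scaled by TMM and tested in edgeR 4.0.16 by the quasi-likelihood test, with 4 groups in 1 fit and Benjamini-Hochberg adjustment over the genes tested at a threshold of 0.05. The common biological coefficient of variation was 0.458 with 4 residual degrees of freedom. The contrasts were irradiated minus untreated in each genotype, their mean, their difference (knockdown minus WT), and knockdown minus WT within each treatment. In simulated counts 200 changed genes were drawn from those with an average log2 CPM of at least 5, and the spread of each gene followed its expression level. Of their changes, 56% of 2-fold and 100% of 4-fold were recovered with 15 false calls, and with no changed gene there were 0 calls. Recovery among genes of fewer counts was not simulated.

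The 26 gene lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists, and beside it with an estimated correlation and with fry, which tests whether a list moves on balance one way. The lists, contrasts, cell filters, tests and most alternatives were chosen before the data were examined. The rule for named genes, also set then, took 3 sets per contrast. The first was genes past the threshold with an average log2 CPM of at least 5 and no overlap between the compared libraries, the 8 with the largest change in each direction (5 for the difference between genotypes). The second was the 3 members with the smallest p of each list that passed camera. The last was a fixed set in every contrast, among them ATM, CDKN1A, MDM2, GDF15, PLK1, CCNB1, CDC20 and MKI67. Some genes and 1 list that the rule takes are not used here. Genes named outside the rule, such as CCL2, FTL and PTPRC, were chosen after their values were seen.

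For measures per cell, counts were thinned to 69000 per cell with a fixed seed, which 330 kept cells reached and 33 did not. Phases, variability and shares of counts were compared between libraries by an exact permutation of treatment within genotype, two-sided, with 36 arrangements and a smallest p of 0.0556. Clustering in scanpy 1.11.5 used log-transformed counts per 10000, 2000 variable genes, 30 components, 15 neighbours and a Leiden resolution of 1, and cells rather than libraries set the clusters, so their sizes were not compared. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Alternatives were DESeq2's size factors or no scaling, no filter or a higher one, DESeq2's Wald test, limma on the mean CPM per cell, fits of the compared groups alone, all barcodes, at least 3000 genes per cell, no cells above 2 times the median total, and each library left out. Neither alternative scaling moved the median log2 change of all genes by more than 0.0698.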

Results

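Single cells of MDA-MB-231, a human triple-negative breast cancer line, were sequenced to follow how transcript levels change after ionizing radiation with and without knockdown of ATM, the kinase that starts the response to DNA double-strand breaks. The 8 libraries formed 4 groups of 2: untreated wild type (WT), WT given 5 Gy and cultured for 4 h, untreated ATM knockdown, and ATM knockdown given the same dose and time. After filtering, 363 of 378 cells were kept, and all 15 cells left out came from the knockdown libraries. The kept cells of the untreated WT libraries held 24256471 and 19973545 counts, and those of the irradiated WT libraries 9321268 and 19675584. The untreated knockdown libraries held 15286467 and 17661327 counts, and the irradiated knockdown libraries 19813882 and 19392992. Single cells ranged from 9411 to 2241907 counts. The library, not the cell, was the unit of replication, and the labels do not say whether the 2 libraries of a group came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical only. All WT libraries shared a title suffix and all knockdown libraries shared another, so any difference in handling between the sets cannot be separated from genotype. Levels are counts scaled to CPM (per 1e6 counts of the library), given as mean ± SD over the 2 libraries of a group, fold changes are on the log2 scale with their SE, and adjusted p-values are from edgeR's quasi-likelihood test unless camera is named.

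ATM transcript levels showed how far the libraries carried the knockdown. ATM (ENSG00000149311.18, chromosome 11, 108222484 to 108369102, GRCh38) was at 58.2 and 31.9 CPM in the untreated WT libraries and at 29.1 and 33.9 CPM in the irradiated WT libraries. The untreated knockdown libraries held 13.6 and 31.9 CPM, and the irradiated knockdown libraries 12.6 and 13.9 CPM. Replicate 2 of the untreated knockdown was therefore level with the WT libraries in summed counts. A single cell held 24.9% of its ATM counts. After thinning, ATM was detected in 53.8% to 67.4% of cells in the 4 WT libraries and in 30.2% to 37.5% of cells in the 4 knockdown libraries. The log2 difference between genotypes was -0.98 (SE 0.413) without irradiation, with an adjusted p of 0.157, and -1.25 (SE 0.419) after irradiation, with an adjusted p of 0.109, so neither passed the test. A contrast over both treatments, chosen after these values were seen, gave -1.12 (SE 0.294, adjusted p = 0.0168).

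Irradiation of WT cells raised FAM111B, CDT1 and MCM4 and lowered AKR1B1, SLC5A3 and CST4, among 205 genes that passed. FAM111B (ENSG00000189057.10, chromosome 11, 59107185 to 59127410), which encodes a protease needed for replication, rose from 12.6 ± 2.58 to 55.2 ± 14.5 CPM (n = 2 and 2; log2 change 2.13, SE 0.339, adjusted p = 0.00758). The replication licensing factor CDT1 rose from 17.8 ± 3.74 to 56.0 ± 15.3 CPM and the helicase subunit MCM4 from 40.96 ± 10.7 to 118 ± 14.4 CPM. MCM10, which takes part in starting replication, CHAF1B, a subunit of the chromatin assembly factor, C19orf48 and FARSB, a subunit of phenylalanyl-tRNA synthetase, also rose, with log2 changes of 1.65, 1.56, 1.53 and 1.47. AKR1B1 (ENSG00000085662.13, chromosome 7, 134442350 to 134459284), the aldose reductase of the polyol pathway, fell from 7651 ± 17.3 to 1535 ± 128 CPM (log2 change -2.32, SE 0.102, adjusted p = 5.3e-09). SLC5A3, the sodium/myo-inositol transporter, fell from 1432 ± 177 to 305 ± 140 CPM. Its annotated span (chromosome 21, 34073570 to 34106262) overlaps another gene, and the strand use of the counting is not stated. The cysteine protease inhibitors CST4 and CST1 fell, with log2 changes of -4.32 and -3.40, as did the transcription factor SOX4 at -3.92 and TPD52L1 at -2.23. The reductases AKR1C2 and AKR1C1, paralogs whose reads are hard to tell apart, fell with log2 changes of -3.49 and -2.71. ATP6V0A2, a subunit of the vacuolar proton pump, had a log2 change of 2.73 with an adjusted p of 0.0315, but its irradiated libraries stood at 228 and 32.5 CPM and the call was lost without irradiated WT replicate 1, at an adjusted p of 0.634.

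Among the 26 gene lists fixed before the data were examined, 11 passed camera in WT with its preset correlation and none with an estimated correlation. Here and below, each list has both adjusted p-values, the latter second. All 35 measured members of the G1/S and DNA replication list were higher after irradiation, 14 passed over all genes and 30 adjusted over the list alone, and the median log2 change was 1.06 (camera adjusted p = 8.9e-32, and adjusted p = 0.362 with an estimated correlation). The histone mRNA-binding protein SLBP rose from 104 ± 3.89 to 280 ± 76.2 CPM, the licensing inhibitor GMNN from 103 ± 11.6 to 204 ± 33.2 CPM, and the checkpoint adaptor CLSPN from 67.0 ± 16.8 to 172 ± 73.5 CPM. Of the 74 ribosomal protein genes, 68 were higher, 9 passed over all genes and 37 passed upward adjusted over the list alone, with a median of 0.31 (adjusted p = 7.2e-27, and 0.423 with an estimated correlation). RPL35, RPS2 and RPL7 rose by 0.60, 0.63 and 0.61, and the annotation names 8, 20 and 61 pseudogenes of these genes. Homologous recombination and Fanconi anaemia genes passed upward (21 of 24 members higher, median 0.78, adjusted p = 0.000201, and 0.423 with an estimated correlation), although no member passed over all genes and 3 passed upward and 1 downward adjusted over the list alone. RBBP8 and FANCB stood at log2 differences of 1.28 and 1.89 and MUS81 at -0.88. The nuclear-encoded respiratory chain (28 of 41 higher, median 0.11, adjusted p = 0.00355 and 0.597; ATP5G1 rose by 0.70) and the mitochondrially encoded genes (9 of 13 higher, median 0.10, adjusted p = 0.0285 and 0.502) passed upward by small amounts.

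Lists that passed downward in WT were the immediate early genes (18 of 27 lower, median -0.27, adjusted p = 0.00162, and 0.495 with an estimated correlation), senescence-associated secretion (19 of 22 lower, median -0.33, 0.000841 and 0.423), hypoxia and glycolysis (21 of 30 lower, median -0.23, 0.000836 and 0.495) and cholesterol synthesis (18 of 22 lower, median -0.33, 0.000595 and 0.495). Also lower were luminal breast epithelial markers (11 of 13 lower, median -0.36, adjusted p = 0.000486 and 0.423) and the interferon response (17 of 27 lower, median -0.32, 0.0176 and 0.543). Their members that passed over all genes numbered 2, 3, 2, 1, 1 and 0 in that order. JUNB, an AP-1 transcription factor, fell from 112 ± 5.20 to 48.3 ± 6.80 CPM and the MAP kinase phosphatase DUSP4 from 451 ± 106 to 202 ± 62.4 CPM. PLAT, which encodes tissue plasminogen activator, fell with a log2 change of -1.38, the chemokine CXCL1 with -2.94 and the angiogenic factor VEGFA with -1.499. NDRG1, the sterol oxidase gene MSMO1 and the tight junction gene CLDN4 fell with log2 changes of -1.24, -0.80 and -1.52. Camera's adjusted p-values of the lists that did not pass were 0.0642 for G2/M and mitosis, 0.0825 for autophagy and lysosome, 0.124 for oxidative stress and NRF2 targets, 0.15 for non-homologous end joining, for NF-kB targets and for leukocyte markers, 0.156 for damage sensing and checkpoint kinases, and 0.212 for epithelial-mesenchymal transition. They were 0.693 for embryonic kidney line markers and 0.782 for the unfolded protein and ATF4 response. Apoptosis regulators, replication-dependent histones and basal epithelial markers stood at 0.808, and heat shock proteins at 0.916. The result of the remaining list is not used here. The heat shock and apoptosis lists had a median and a mean of opposite sign.

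In all, 205 of 12456 genes passed in WT, 113 upward and 92 downward, and 1734 had an unadjusted p below the threshold. The count fell to 33, with 5 upward, when only the 4 WT libraries were fitted, stood at 129 and 89 without irradiated WT replicates 1 and 2, and at 376 and 375 without untreated knockdown replicates 1 and 2. Downward calls outnumbered upward ones with an average log2 CPM of at least 5 (167 against 155), without untreated WT replicate 1 (108 against 101) and without irradiated knockdown replicate 1 (129 against 124). Of the 31 named genes that passed in WT, 9 passed under every alternative, and the 21 lost in the fit of the WT libraries alone had adjusted p-values of 0.0543 to 0.146. Without irradiated WT replicate 2, 13 of them lost their call (CDT1, CHAF1B, MCM10, MCM4, CLSPN, GMNN, ATP5G1, CST1, CXCL1, DUSP4, JUNB, MSMO1 and PLAT, at 0.0661 to 0.355). Without irradiated WT replicate 1, 9 did (ATP6V0A2, C19orf48, FARSB, JUNB, MSMO1, NDRG1, RPL7, TPD52L1 and VEGFA, at 0.0519 to 0.634). Without untreated WT replicate 1, 6 did (ATP5G1, CHAF1B, JUNB, RPL7, TPD52L1 and VEGFA, at 0.0553 to 0.172), and without untreated WT replicate 2, CDT1 did (at 0.0775). Without cells above 2 times their library's median total, 7 did (ATP6V0A2, CHAF1B, CXCL1, FARSB, GMNN, MSMO1 and TPD52L1, at 0.0669 to 0.806) and 130 genes passed. ATP6V0A2, CXCL1 and JUNB missed it on the mean CPM per cell with limma (0.0989 to 0.109), CST1 in DESeq2's Wald test (0.0501) and ATP5G1 with DESeq2's size factors (0.0536). FAM111B, AKR1B1, AKR1C1, AKR1C2, SLC5A3, CST4, SOX4, SLBP and CLDN4 were the 9. Without irradiated WT replicate 2 the interferon list turned upward (adjusted p = 0.0483), and the immediate early, mitochondrially encoded and hypoxia lists no longer passed (0.351, 0.341 and 0.126). Without untreated WT replicate 1 the interferon, immediate early, mitochondrially encoded, nuclear respiratory chain and cholesterol lists did not pass (0.0648 to 0.701), and without untreated WT replicate 2 the hypoxia list did not (0.0591). The mitochondrially encoded list also missed the threshold without either untreated knockdown library (0.0614 and 0.0603) and with DESeq2's size factors (0.0596).

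**Figure D1:**
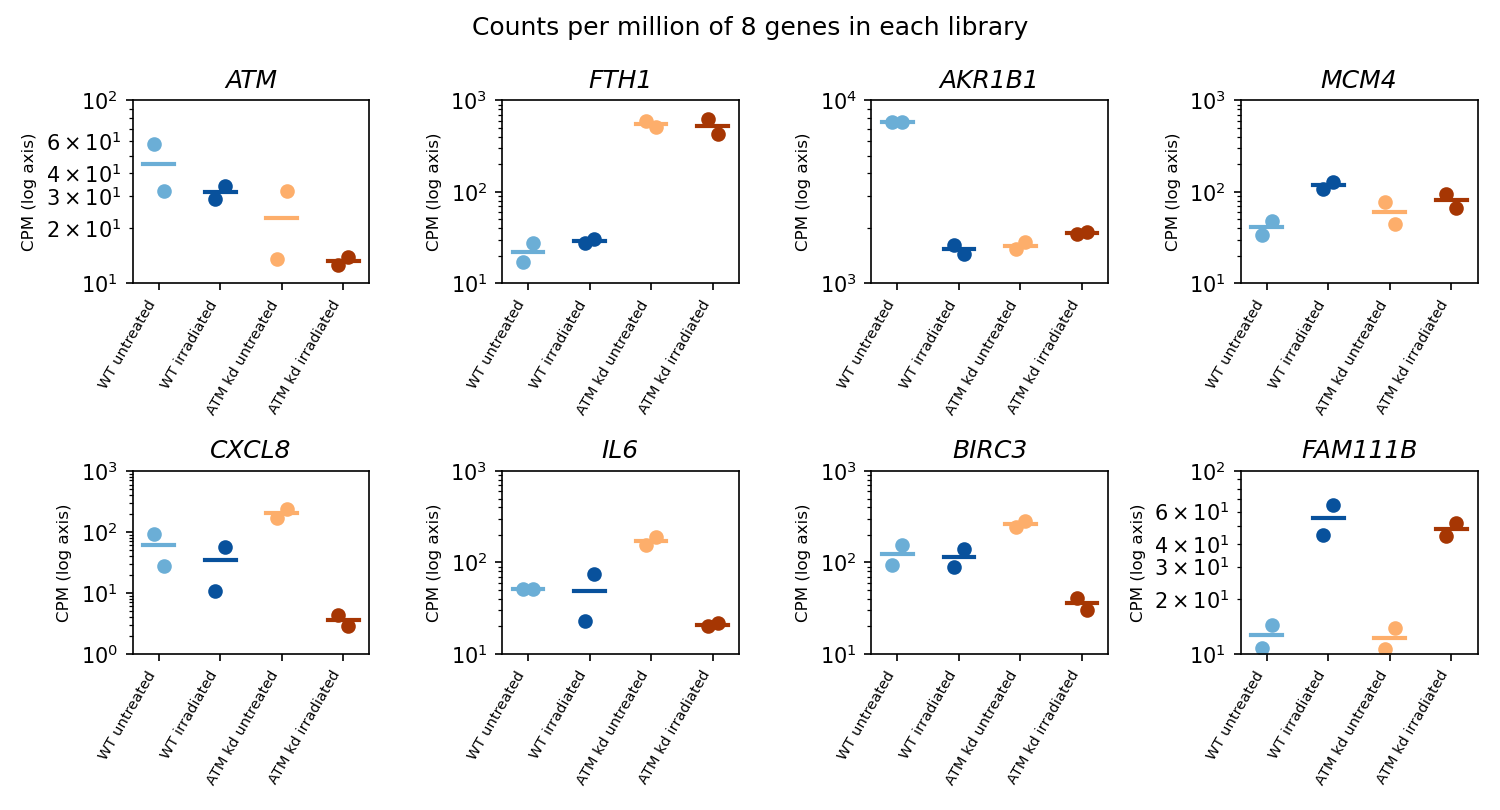
Levels of 8 genes in each of the 8 libraries, in CPM on a log axis. Each point is a library and each horizontal bar the group mean; AKR1B1 stood at 7651 CPM in untreated WT and at 1535 to 1883 CPM in the other groups, and FTH1 at 22.2 and 29.2 CPM in WT against 550 and 532 CPM in the knockdown.

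In ATM knockdown cells irradiation lowered inflammatory cytokine and chemokine genes. CXCL8 (ENSG00000169429.10, chromosome 4, 73740506 to 73743716), the neutrophil chemoattractant interleukin 8, fell from 203 ± 45.8 to 3.64 ± 1.02 CPM (n = 2 and 2; log2 change -5.80, SE 0.696, adjusted p = 0.00102). The chemokine CXCL2 fell from 148 ± 17.1 to 2.60 ± 1.58 CPM, the cytokine IL6 from 173 ± 23.7 to 20.9 ± 1.03 CPM and the growth factor gene CSF2 from 201 ± 34.05 to 16.4 ± 12.7 CPM. BIRC3, an NF-kB target that encodes an inhibitor of apoptosis, fell from 263 ± 30.7 to 35.7 ± 7.36 CPM. TNFAIP2, the death ligand gene TNFSF10 and the mitotic kinesin gene KIF20A fell with log2 changes of -2.44, -2.34 and -2.29. Upward calls were 4 in number, and among the named genes FAM111B rose from 12.3 ± 2.30 to 48.1 ± 5.26 CPM, the matrix protein gene THBS1 from 745 ± 222 to 1831 ± 227 CPM, and the actin gene ACTG1, with 20 named pseudogenes, from 3086 ± 146 to 4688 ± 402 CPM.

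Of the 26 measured NF-kB targets, 24 were lower in irradiated knockdown cells, 10 passed over all genes and 16 adjusted over the list alone, and the median log2 change was -1.85 (camera adjusted p = 1.2e-27). This list also passed with an estimated correlation (adjusted p = 0.0215), the only list to do so in this contrast, and in fry's direction test (0.012). G2/M and mitosis genes were lower in 44 of 46 cases (median -0.78, adjusted p = 1.3e-22, and 0.298 with an estimated correlation), with KIF20A the only call over all genes and 26 calls adjusted over the list alone. The mitotic cyclin CCNB2 and GTSE1 stood at -1.25 and -1.34, neither past the threshold. At thinned depth mitochondrial transcripts, a sign of RNA quality, made up 13.2% ± 0.931 of the counts in untreated and 11.3% ± 0.522 in irradiated knockdown libraries. The G1/S list passed upward with a smaller median of 0.26 (29 of 35 higher, adjusted p = 0.000212, and 0.465 with an estimated correlation), and TIPIN, GMNN and CDC6 stood at 1.61, 0.68 and 0.85, none of them past the threshold. Heat shock proteins (9 of 11 higher, median 0.22, adjusted p = 0.000259, and 0.137 with an estimated correlation), ribosomal proteins (56 of 74 higher, median 0.08, 0.000505 and 0.664) and epithelial-mesenchymal transition genes (22 of 27 higher, median 0.21, 0.000984 and 0.137) passed upward.

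Further lists passed downward in knockdown cells: immediate early genes (24 of 27 lower, median -0.38, adjusted p = 6.2e-07, and 0.183 with an estimated correlation), mitochondrially encoded genes (12 of 13 lower, median -0.16, 6.2e-07 and 0.179), oxidative stress and NRF2 targets (20 of 22 lower, median -0.27, 5.5e-05 and 0.179) and the unfolded protein and ATF4 response (17 of 22 lower, median -0.36, 0.000998 and 0.298). So did senescence-associated secretion (13 of 22 lower, median -0.26, adjusted p = 0.00253 and 0.23), hypoxia and glycolysis (22 of 30 lower, median -0.19, 0.0026 and 0.465) and apoptosis regulators (17 of 27 lower, median -0.14, 0.0126 and 0.338). The replication-dependent histone list, drawn up with core and linker histone genes, passed as well (9 of 11 lower, median -0.48, 0.0302 and 0.386). How well 3' mRNA libraries capture histone transcripts was not tested. Of these, the secretion list held 4 calls over all genes, among them CXCL8, CXCL2 and CXCL1, and the apoptosis list 1, BIRC3. The homologous recombination, end joining, luminal and basal lists did not pass and had a median and a mean of opposite sign.

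In the knockdown 28 genes passed, 4 upward and 24 downward, with 1104 at an unadjusted p below the threshold. The count rose to between 44 and 142 when any 1 library was left out, each by more than 1.5 times, to 142 without untreated WT replicate 2 and 139 without untreated WT replicate 1. Of 12 named genes that passed, 10 did so under every alternative; FAM111B missed the threshold without irradiated knockdown replicate 2 or untreated knockdown replicate 1, and KIF20A without the former (adjusted p-values of 0.0586 to 0.07). FAM111B also missed it on the mean CPM per cell with limma (0.0647) and without cells above 2 times their library's median total (0.0661). Without untreated knockdown replicate 1 the unfolded protein, apoptosis, secretion and hypoxia lists did not pass (0.0503 to 0.35), without untreated knockdown replicate 2 the ribosomal and histone lists did not (0.167 and 0.176), and without irradiated knockdown replicate 1 the apoptosis, secretion, ribosomal and histone lists did not (0.0884 to 0.764).

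**Figure D2:**
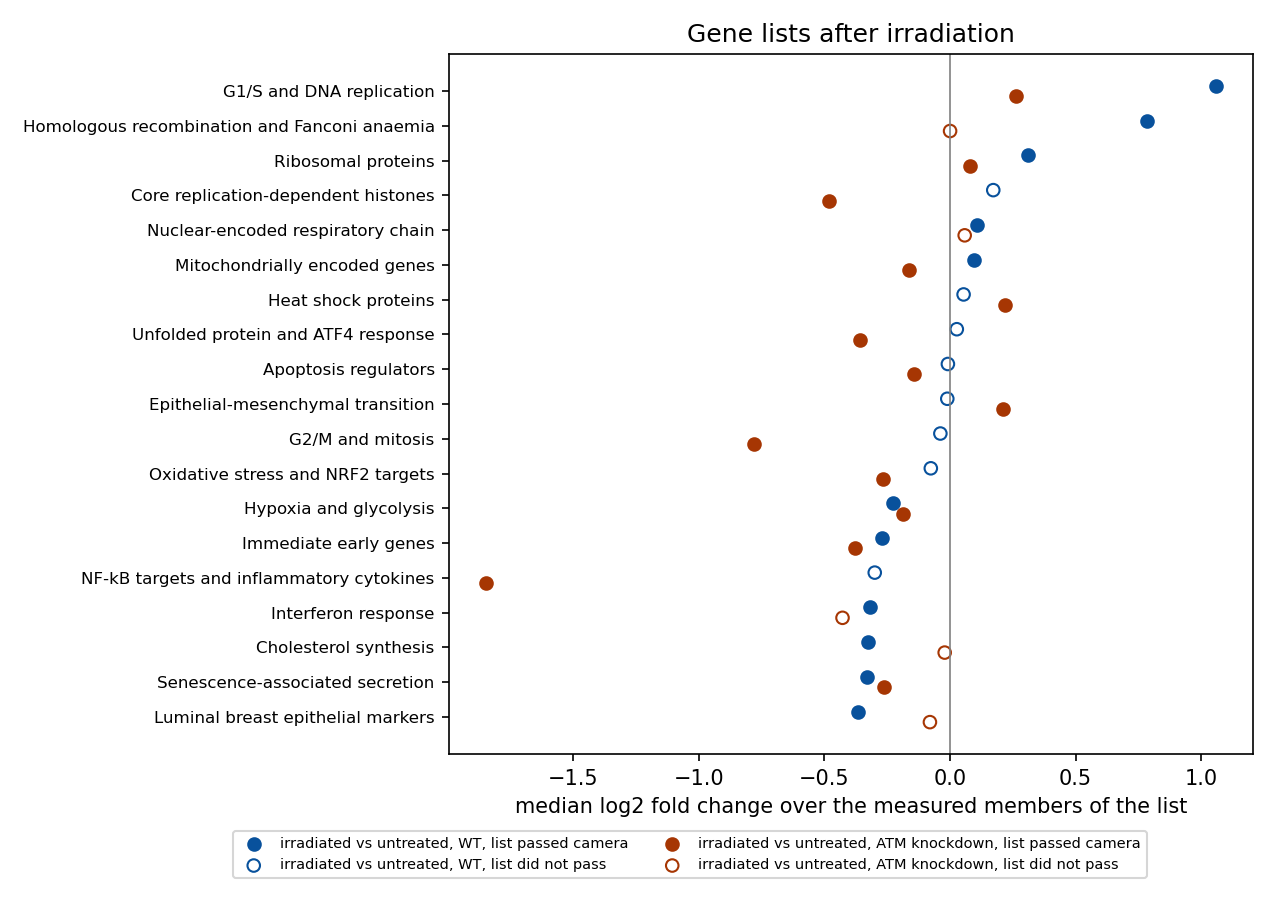
Median log2 fold change after irradiation over the measured members of each gene list that passed camera in at least one genotype, for WT and ATM knockdown. Filled points passed camera with the preset correlation and open points did not; the NF-kB list stood at -1.85 in the knockdown and -0.30 in WT, and the G1/S list at 1.06 in WT and 0.26 in the knockdown.

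Averaged over both genotypes, irradiation raised FAM111B by 2.05 (SE 0.239, adjusted p = 0.000477), MCM10 by 1.41, the replication-coupled ubiquitin ligase gene DTL by 1.28, RPL22L1 by 1.12, C19orf48 by 1.07, the amino acid transporter gene SLC7A5 by 1.06, and the nucleolar genes NOL6 and NOP16 by 1.06 and 1.01. It lowered CST4, CST1, AKR1C1 and TNFAIP2, with log2 changes of -2.77, -2.47, -1.83 and -1.62, and ZBED6CL, SLCO4A1, SLC5A3 and the sialic acid synthesis gene GNE, with -1.54, -1.43, -1.42 and -1.41. In this average 186 genes passed, 80 upward and 106 downward, with 1811 at an unadjusted p below the threshold, and without untreated WT replicate 2 the count was 375. Calls of 8 of the 36 named genes that passed were lost without some library. RPL10 was lost without any library but untreated WT replicate 2, and HSPH1 without either irradiated WT library, either irradiated knockdown library or untreated knockdown replicate 2. DTL was lost without irradiated WT replicate 2, RPL22L1 without irradiated knockdown replicate 1, RPL27 without irradiated knockdown replicate 2, and NOL6 without irradiated WT replicate 2 or irradiated knockdown replicate 1. RPS27A was lost without these 2 or untreated knockdown replicate 2, and VEGFA without irradiated knockdown replicate 1 or replicate 1 of either WT group, all at adjusted p-values of 0.0505 to 0.134. MCM10 and HSPH1 were lost on the mean CPM per cell with limma (0.133 and 0.0849), RPL22L1 and NOL6 without cells above 2 times their library's median total (0.117 and 0.0907), and RPL10 with DESeq2's size factors (0.0561). The ubiquitin ligase gene MDM2, the cell cycle inhibitor gene CDKN1A and the stress cytokine gene GDF15 had log2 changes of -0.19, -0.23 and -2.41 (SE 0.273, 0.22 and 0.695), none past the threshold in this average or in either genotype.

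In the average 14 lists passed, and none with an estimated correlation. G1/S genes were higher in 35 of 35 cases (median 0.66, camera adjusted p = 3.6e-25, and adjusted p = 0.196 with an estimated correlation), with 8 calls, among them GMNN, SLBP and CDC6. Ribosomal proteins were higher in 66 of 74 (median 0.20, adjusted p = 2.3e-22, and 0.311 with an estimated correlation), with RPL27, RPS27A and RPL10 called. Homologous recombination genes were higher in 19 of 24 (median 0.44, adjusted p = 0.0026 and 0.388, no call), the nuclear respiratory chain in 30 of 41 (median 0.08, 0.00373 and 0.526, no call) and heat shock proteins in 8 of 11 (median 0.16, 0.0384 and 0.311), where the 1 call, HSPH1, fell (log2 change -0.52). NF-kB targets were lower in 23 of 26 cases (median -1.29, adjusted p = 2.3e-15, and 0.104 with an estimated correlation), with 10 calls, among them CXCL1, TNFAIP2 and BIRC3. G2/M genes were lower in 42 of 46 (median -0.45, adjusted p = 3.4e-14 and 0.455, ECT2 and KIF20A called) and immediate early genes in 23 of 27 (median -0.33, 4.3e-07 and 0.237, JUNB and DUSP4 called). Secretion genes were lower in 19 of 22 (median -0.84, adjusted p = 7.4e-06 and 0.196, 6 calls) and hypoxia genes in 20 of 30 (median -0.15, 3.2e-05 and 0.388, NDRG1 and VEGFA called). NRF2 targets were lower in 18 of 22 (median -0.11, adjusted p = 0.00063 and 0.274), and their 3 calls were the paralogs AKR1C1, AKR1C2 and AKR1C3. Cholesterol synthesis (16 of 22 lower, adjusted p = 0.00291 and 0.501), the interferon response (20 of 27 lower, 0.00359 and 0.517) and luminal markers (8 of 13 lower, 0.00652 and 0.388) held 0, 0 and 1 calls, the last CLDN4 with a log2 change of -1.31. Without irradiated WT replicate 2 the interferon list stood at a camera adjusted p of 0.696, and the homologous recombination and luminal lists at 0.0673 and 0.0846. The interferon list missed the threshold without untreated WT replicate 1 (0.0555) and the luminal list without untreated knockdown replicate 2 (0.101). The respiratory chain list missed it without untreated WT replicate 1 or untreated knockdown replicate 2 (0.374 and 0.208), and the heat shock list without any library but irradiated knockdown replicate 2 (0.0607 to 0.226) and with DESeq2's size factors (0.0506). The end joining, checkpoint kinase, basal and leukocyte lists did not pass and had a median, mean or test of differing sign.

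The response to irradiation differed between the WT and knockdown libraries for 23 genes by the interaction term. Of these, 13 were upward and 10 downward, and 1183 genes had an unadjusted p below the threshold. For CXCL2, CXCL8, CSF2, IL6 and BIRC3 the log2 change in the knockdown minus that in WT was -6.45, -5.002, -4.73, -3.004 and -2.77 (adjusted p-values of 0.00531 to 0.0367). In irradiated WT libraries these genes varied widely, CXCL8 for example at 10.9 and 57.5 CPM. AKR1B1, AKR1C2, PLAT, the bicarbonate transporter gene SLC4A7 and the pregnancy-specific glycoprotein gene PSG5 had positive differences of 2.55, 3.02, 2.67, 2.58 and 2.28. AKR1B1 stood at 1606 ± 97.4 CPM in untreated and 1883 ± 25.2 CPM in irradiated knockdown cells, against its fall in WT. The untreated knockdown thus already lay near the irradiated WT level, and untreated WT stood apart. AKR1B1 and SLC4A7 were both called lower than in untreated WT in irradiated WT and in the untreated knockdown. Such values do not separate a response missing in the knockdown from a state of the untreated WT libraries. No named call was lost when a library was left out, but the number of calls rose to 128 without untreated WT replicate 1, with 49 upward and 79 downward, and to 44, 51, 65, 52 and 48 without irradiated WT replicate 1, untreated WT replicate 2, untreated knockdown replicates 1 and 2 and irradiated knockdown replicate 1. AKR1C2, SLC4A7, PSG5, PSAT1 and THBS1 missed the threshold without cells above 2 times their library's median total (0.172 to 0.46). AKR1C2, IL6, PSAT1, PSG5 and THBS1 missed it on the mean CPM per cell with limma (0.112 to 0.236). DESeq2's Wald test gave AKR1C2 no adjusted p. Of the 26 lists, 12 passed camera on this term, and with an estimated correlation none did (adjusted p-values of 0.135 to 0.531). NF-kB targets were lower in 21 of 26 cases (median -1.43, adjusted p = 2.5e-13, and 0.135 with an estimated correlation, 6 calls) and G1/S genes in 34 of 35 (median -0.78, 8.1e-15 and 0.265, no call), with SLBP, RRM1 and TYMS at -1.10, -0.97 and -0.98. G2/M genes had a median of -0.72 with 42 of 46 lower (adjusted p = 6.8e-08, and 0.531 with an estimated correlation, no call), ribosomal proteins -0.23 with 63 of 74 lower (3e-11 and 0.461, no call) and mitochondrially encoded genes -0.21 with 11 of 13 lower (2.3e-07 and 0.265, no call). The serine synthesis gene PSAT1, the chaperone gene HSPH1 and THBS1 were the calls within the unfolded protein, heat shock and epithelial-mesenchymal lists, with differences of -2.06, 1.47 and 1.28. These lists had medians of -0.35 (18 of 22 lower, adjusted p = 0.033, and 0.461 with an estimated correlation), 0.09 (7 of 11 higher, 0.0141 and 0.265) and 0.34 (22 of 27 higher, 0.000386 and 0.152). Homologous recombination (median -0.64, 18 of 24 lower, adjusted p = 0.0039 and 0.461), apoptosis (-0.24, 18 of 27 lower, 0.0383 and 0.461), cholesterol (0.26, 16 of 22 higher, 0.0105 and 0.505) and luminal genes (0.29, 9 of 13 higher, 0.0112 and 0.461) passed as well. The interferon and NRF2 lists did not pass and had a median, mean or test of differing sign.

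Without irradiation, knockdown and WT libraries differed in many genes, and this comparison includes anything else that differed between the sets. FTH1 (ENSG00000167996.15, chromosome 11, 61959718 to 61967660), the heavy chain of the iron store ferritin, was at 22.2 ± 7.37 CPM in WT and at 550 ± 61.4 CPM in the knockdown (n = 2 and 2; log2 difference 4.63, SE 0.252, adjusted p = 3.8e-08), and the annotation names 25 pseudogenes of it. The ferritin light chain gene FTL lay between 6391 and 8156 CPM in all 8 libraries. HMOX1, which breaks down haem, was at 8.82 ± 2.75 and 60.7 ± 12.1 CPM, and the cytokine IL24, CSF2, the perlecan gene HSPG2, the metallothionein MT1E, G0S2 and CXCL2 were higher in the knockdown by 4.28, 2.78, 2.70, 2.63, 2.57 and 2.50. SLC5A3 was lower, at 1432 ± 177 in WT and 62.4 ± 13.4 CPM in the knockdown (log2 difference -4.52). The keratin KRT81, AGFG2, the lipopolysaccharide co-receptor CD14, AKR1C1, AKR1C2 and the cytokine TNFSF15 stood at -4.26, -3.38, -3.22, -3.18, -3.18 and -3.11, and the interferon-induced OASL at -6.08. OASL stood at 138 CPM in untreated WT replicate 1 and at 6.00 CPM in replicate 2, and its call was lost without replicate 1. The calls of CXCL2 and TNFSF15 were lost in DESeq2's Wald test (0.074 and 0.155). TNFSF15 was also lost when only these 4 libraries were fitted (0.103) and without cells above 2 times their library's median total (0.15). The cell cycle inhibitor gene CDKN1A was higher in the knockdown by 1.40 (42.1 ± 19.3 against 111 ± 27.2 CPM, adjusted p = 0.0109), and this call was lost without untreated WT replicate 2, as was that of CLSPN (0.0535 to 0.13). CCL2, a monocyte chemoattractant, had 2025 counts in untreated WT and 0 in the untreated knockdown libraries, at least 496-fold lower against a floor of 3 counts over the group, or 248-fold without untreated WT replicate 1 and 744-fold without replicate 2. A single WT cell held 74.6% of the counts of replicate 1.

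Between the untreated genotypes 1238 genes passed, 602 higher and 636 lower in the knockdown, and 718 when only these 4 libraries were fitted. Higher genes outnumbered lower ones without scaling (692 against 565), on the mean CPM per cell with limma (783 against 729) and without cells above 2 times the median total (545 against 522). Of the lists, 10 passed and none with an estimated correlation. Those that passed upward were the NF-kB targets (20 of 26 higher, median 1.08 with or without CCL2 at its bound, camera adjusted p = 0.000116, and adjusted p = 0.363 with an estimated correlation, 7 calls up and 1 down) and the unfolded protein and ATF4 response (20 of 22 higher, median 0.78, 1.7e-05 and 0.363, 6 calls). Their members LIF, IL6, PSAT1, HSPA5 and XBP1 stood at 2.99, 1.76, 2.15, 1.20 and 0.89. G1/S genes (27 of 35 higher, median 0.37, adjusted p = 0.0104, and 0.666 with an estimated correlation, 1 call up, CLSPN, and 1 down), mitochondrially encoded genes (8 of 13 higher, median 0.23, 0.0104 and 0.499, 5 calls up and 1 down) and ribosomal proteins (48 of 74 higher, median 0.11, 0.0114 and 0.749, 13 calls up and 5 down) also passed upward. MT-ATP8, MT-CYB and MT-CO2 stood at 1.13, 0.53 and 0.46. Lists that passed downward were hypoxia and glycolysis (25 of 30 lower, median -0.73, adjusted p = 6.6e-09, and 0.363 with an estimated correlation, 15 calls down and 1 up) and the nuclear respiratory chain (34 of 41 lower, median -0.21, 4.5e-06 and 0.562, 13 calls down and 2 up). The glycolytic genes ENO1 and PKM stood at -1.11 and -0.95, BNIP3L at -1.38, and the respiratory chain genes COX8A, COX6A1 and UQCR11 at -1.83, -1.41 and -1.29. Luminal markers (10 of 13 lower, median -0.88, adjusted p = 0.0085, and 0.499 with an estimated correlation, the keratins KRT7, KRT8 and KRT18 at -1.55, -0.88 and -0.95), the interferon response (18 of 27 lower, median -0.67, 0.017 and 0.648, 6 calls) and leukocyte markers (5 of 5 lower, median -3.22, 0.0211 and 0.363) also passed downward, the last with CD14 as the only call. The pan-leukocyte marker PTPRC had a thinned count in 1 of 43 cells of untreated WT replicate 1 and in 0 of 46 of untreated WT replicate 2. The Clopper-Pearson upper bounds of 12.3% and 7.71% limit the share of cells with such a count, not of cells that express the gene. The calls of HERC5 and OASL were lost without untreated WT replicate 1 (0.201 and 0.119), of HERC5 also on the mean CPM per cell with limma (0.123), of BST2 without untreated knockdown replicate 2 (0.0734), and of CLSPN without untreated knockdown replicate 1 (0.0575). The autophagy and histone lists, which did not pass, had a median and a mean of opposite sign.

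After irradiation, 635 genes differed between the genotypes, 271 higher and 364 lower in the knockdown. Higher genes outnumbered lower ones without scaling (334 against 309) and on the mean CPM per cell with limma (378 against 362). FTH1 was at 29.2 ± 2.00 CPM in WT and 532 ± 138 CPM in the knockdown (log2 difference 4.19, SE 0.248, adjusted p = 3.9e-07). PDZK1IP1, HMOX1, HSPG2, APBB1IP, TRIM29 and MTRNR2L12, the last a nuclear copy of a mitochondrial sequence, were higher by 3.08, 2.88, 2.78, 2.44, 2.16 and 2.01. The calcium-binding protein gene S100A2 stood at 501 ± 4.88 CPM in WT and 63.04 ± 23.5 CPM in the knockdown (log2 difference -2.99), and CXCL2, CXCL8, SLCO4A1, SLC5A3 and TNFSF10 stood at -3.95, -3.25, -2.93, -2.91 and -2.88. The interferon-induced genes IFIT1 and IFIT2 stood at -4.89 and -3.36, and IFIT1 stood at 226 and 48.9 CPM in the irradiated WT libraries. CCL2 had 508 counts in irradiated WT and 0 in the irradiated knockdown, at least 280-fold lower against the same floor, or 169-fold without irradiated WT replicate 1. Of the lists, 9 passed and none with an estimated correlation. G2/M genes were lower in 45 of 46 cases (median -0.90, camera adjusted p = 7.6e-10, and adjusted p = 0.632 with an estimated correlation, 11 calls) and G1/S genes in 30 of 35 (median -0.39, 5.5e-07 and 0.555, 3 calls). The mitotic genes PTTG1, BIRC5 and GTSE1 stood at -1.33, -1.33 and -1.69, and the G1/S genes TYMS and E2F1 at -1.40 and -1.25. The nuclear respiratory chain (36 of 41 lower, median -0.31, adjusted p = 7.4e-13, and 0.555 with an estimated correlation, 12 calls), hypoxia and glycolysis (24 of 30 lower, median -0.56, 3e-09 and 0.555, 9 calls) and NF-kB targets (18 of 26 lower, median -0.95 with or without CCL2 at its bound, 0.00177 and 0.555) passed downward, with LDHA, NFKBIA and TNFAIP2 at -1.12, -1.93 and -2.34. The interferon response (20 of 27 lower, median -0.64, adjusted p = 0.0264 and 0.632) and ribosomal proteins (49 of 74 lower, median -0.11 but mean 0.0027, 0.00288 and 0.697) also passed downward. Cholesterol synthesis (17 of 22 higher, median 0.44, adjusted p = 1.9e-05, and 0.555 with an estimated correlation, 7 calls, ACAT2, MVD and FDPS at 1.78, 1.66 and 1.91) and the unfolded protein response (17 of 22 higher, median 0.47, 0.0133 and 0.555, HSPA5 at 0.70) passed upward. The count of 635 moved by more than 1.5 times without irradiated WT replicates 1 and 2 (378 and 412), irradiated knockdown replicates 1 and 2 (340 and 308) and untreated WT replicate 2 (980). IFIT2, IFI44, IFIH1 and GTSE1 lost their call without irradiated WT replicate 1 (0.0551 to 0.521) and CXCL8, E2F1 and HSPA5 without irradiated WT replicate 2 (0.0864 to 0.143). The same held for E2F1 without irradiated knockdown replicate 1 (0.063), and BIRC5, E2F1, HSPA5 and IFIH1 without irradiated knockdown replicate 2 (0.06 to 0.192). GTSE1 and IFIT2 were also lost on the mean CPM per cell with limma (0.0536 and 0.155). GTSE1 and IFIH1 were lost without cells above 2 times their library's median total (0.106 and 0.306). The luminal and basal lists did not pass and had a median, mean or test of differing sign.

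Cell cycle phases were called in the 330 cells that reached 69000 counts after thinning. The calls came from scores of the G1/S and G2/M lists tested above. Phase shares, list tests and the lists' shares of counts are therefore views of the same genes, not independent evidence. The share of cells called S was 12.2% ± 7.36 in untreated WT and 36.9% ± 12.3 in irradiated WT, and 14.4% ± 9.70 and 38.6% ± 1.97 in the knockdown (SD, n = 2 each). The difference averaged over genotypes was 24.5 percentage points, and every irradiated library lay above every untreated library of its genotype. The share called G2/M was 39.6% ± 13.0 and 38.5% ± 14.5 in untreated and irradiated WT, and 41.4% ± 15.7 and 20.5% ± 0.658 in the knockdown, a mean difference of -11.0 points. The exact permutation of treatment within genotype (36 arrangements, two-sided) gave p = 0.0556 for S, the smallest p this design allows, and p = 0.222 for G2/M. Adjusted over 9 measures these were 0.1 and 0.286. Without each library in turn the G2/M difference ranged from -16.6 to -5.49 points. Shares called G1 fell short of the test as well (difference -13.5 points, exact p = 0.167), with -23.6 points in WT and -3.31 in the knockdown. So did the G2/M share of counts at thinned depth (difference -0.129 points, exact p = 0.278), with -0.0116 in WT and -0.247 in the knockdown. At thinned depth ribosomal protein transcripts made up 1.11 percentage points more of the counts after irradiation, G1/S transcripts 0.115 points more and NF-kB targets 0.123 points less (difference -0.123), each with an exact p of 0.0556, and mitochondrial transcripts differed by -0.786 points (exact p = 0.333), with 0.279 in WT and -1.85 in the knockdown.

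**Figure D3:**
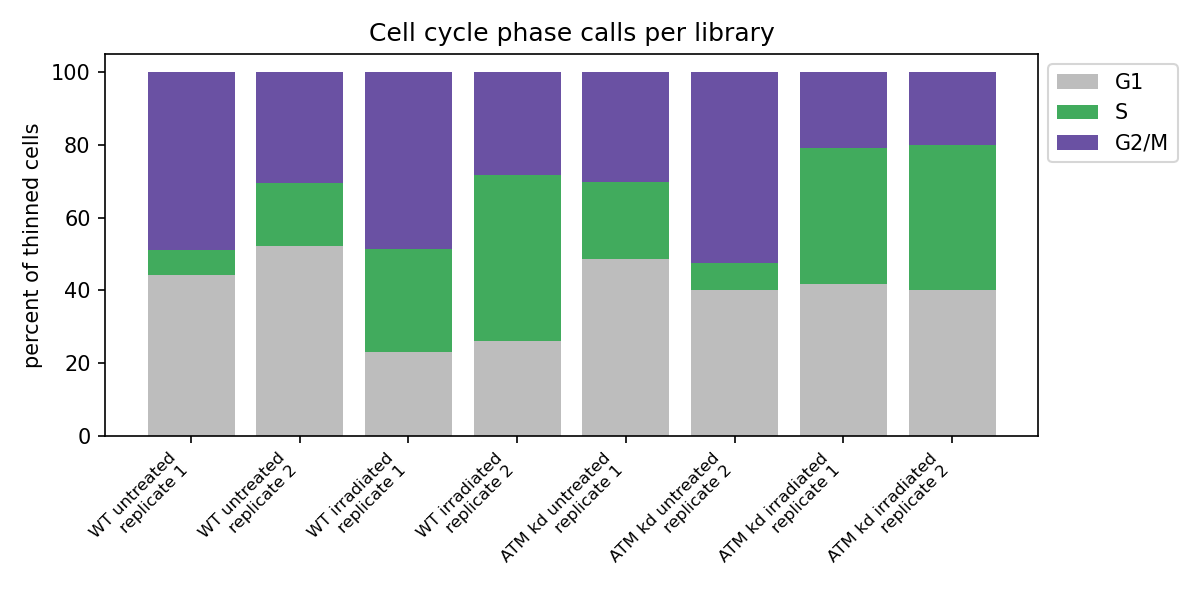
Share of thinned cells called G1, S and G2/M in each of the 8 libraries, in percent, as stacked bars starting at 0. The share called S was 12.2% and 14.4% on average in the untreated WT and knockdown libraries and 36.9% and 38.6% in the irradiated ones.

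The series title names heterogeneity between cells. Cell-to-cell variability was measured as the median over 7340 genes of the squared coefficient of variation minus the inverse of the mean. That inverse is the counting noise of unique molecules. If the counts are reads, which the labels leave open, noise from amplification stays in the measure. This variability was 1.35 ± 0.132 in untreated and 1.02 ± 0.0983 in irradiated WT, and 1.53 ± 0.189 and 0.945 ± 0.0484 in the knockdown (SD, n = 2 each). The mean difference was -0.46, with an exact permutation p of 0.0556 (0.1 adjusted over the 9 measures). The median number of genes detected per thinned cell was higher in each irradiated library than in each untreated library of its genotype, at 5431 and 5390.5 in untreated WT, 5861 and 5573.5 in irradiated WT, 5303 and 5160.5 in the untreated knockdown, and 6022 and 5800.5 in the irradiated knockdown.

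Counts of single genes per cell show how the changes were spread over cells. Their 95% Clopper-Pearson intervals cover only the sampling of cells within a library, not the spread between libraries. CXCL8 was detected in 19 of 33 (57.6%, 39.2% to 74.5%) and 32 of 40 (64.4% to 90.9%) untreated knockdown cells, and in 6 of 43 (5.30% to 27.9%) and 4 of 40 (2.79% to 23.7%) irradiated ones. The 2 libraries of untreated WT held 53.5% and 19.6%, and those of irradiated WT 23.1% and 52.2%. SOX4 was detected in 72.1% (56.3% to 84.7%) and 65.2% (49.8% to 78.6%) of untreated WT cells and in 15.4% (5.86% to 30.5%) and 21.7% (10.9% to 36.4%) of irradiated WT cells, while a single cell held 41.4% and 54.95% of its counts in the untreated WT libraries. CST4 was detected in 37 of 43 and 46 of 46 untreated WT cells and in 14 of 39 and 13 of 46 irradiated ones. FAM111B was detected in 9 of 43 and 10 of 46 untreated and 16 of 39 and 21 of 46 irradiated WT cells, and in 6 of 33 and 8 of 40 untreated and 22 of 43 and 26 of 40 irradiated knockdown cells. CDKN1A was detected in 67.4% and 43.5% of untreated and 59.0% and 58.7% of irradiated WT cells, with Fano factors of 8.53, 5.71, 3.92 and 11.8. GDF15 was detected in 32.6% and 10.9% of untreated and 12.8% and 4.35% of irradiated WT cells, and a single cell held 44.7% of the GDF15 counts of untreated WT replicate 1.

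Clustering of the thinned cells gave 9 clusters, 6 at a Leiden resolution of 0.5 and 13 at 2.0. Clusters 1, 2, 3, 5 and 6 held WT cells apart from 2 knockdown cells in cluster 3, and clusters 7, 8 and 9 held knockdown cells apart from 1 WT cell in cluster 7. Clusters 2, 6 and 7 met the marker rule for a G2/M-like state, with 28, 36 and 41 cells. The first came from untreated WT libraries alone, and 34 of the 36 cells of cluster 6 from irradiated WT libraries. Cluster 9, with 60 cells from the 4 knockdown libraries, had FTH1, CXCL2, SOD2, IL6, IL24 and CXCL8 among its leading genes. It met the rule for an inflammatory-like state with 3 markers, the minimum. Its cells numbered 17 and 17 in the untreated and 14 and 12 in the irradiated knockdown libraries. In the irradiated libraries CXCL2 was detected in 3 of 43 and 2 of 40 thinned cells, so the name need not hold for the irradiated cells of the cluster. Cluster 4, with 26 cells, held cells of all 8 libraries. The other clusters met no rule and were left unnamed.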

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

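The test of the NF-kB fall in cells matched on depth was chosen only after the result was seen, and the other tests in this part were set before, although the patterns that the pseudogene and FTH1 tests bear on were told apart only afterwards, with their bounds kept. The interaction term passed for 23 genes, which marks a difference in the response to irradiation between the WT and knockdown sets of libraries. Genotype cannot be separated from other differences between these sets. Its log2 values, knockdown minus WT, were 3.018 for AKR1C2, 2.669 for PLAT, 2.584 for SLC4A7, 2.547 for AKR1B1 and 2.279 for PSG5. They were -6.449 for CXCL2, -5.002 for CXCL8, -4.732 for CSF2, -3.004 for IL6 and -2.774 for BIRC3. For gene lists past camera's preset correlation, none of which passed with an estimated correlation (adjusted p-values of 0.135 to 0.531), the median difference was -0.7803 for G1/S, -0.7198 for G2/M, -0.6418 for homologous recombination, -1.434 for NF-kB targets, -0.348 for the unfolded protein response, -0.2429 for apoptosis, -0.213 for mitochondrially encoded genes and -0.2307 for ribosomal proteins. It was 0.08591 for heat shock proteins, 0.258 for cholesterol synthesis, 0.338 for epithelial-mesenchymal transition and 0.2851 for luminal markers.

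The fall of NF-kB targets in irradiated knockdown libraries was weighed against a few cells with very high cytokine counts and against depth. The per-cell median of their share of counts differed by -0.1688 percentage points, irradiated minus untreated, and the mean without the 3 highest cells of each library by -0.152, which argues against a few cells. Matching cells on total counts took the gap in median depth from 0.1134 to -0.04182 on the log2 scale. Among matched cells the difference averaged -0.2177 points (at most -0.1848 in 200 draws). The shares came from counts already thinned to 69000 per cell and the gap was small, so matching could change little and does not test depth. Within the untreated knockdown libraries the share moved by only -0.01033 and -0.007777 points per doubling of a cell's counts. A change that the cells of the knockdown undergo with irradiation, or a state of the untreated knockdown cultures such as density or handling, could give the same values, and 2 libraries per group do not separate them.

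FTH1 stood at 17.03 to 30.6 CPM in the WT libraries and 435 to 629.5 CPM in the knockdown libraries. Reads shared with pseudogenes may shift such a gene, but genes with at least 5 named pseudogenes were called between untreated genotypes 1.094 times as often as genes matched on expression (24.5% against 22.4% of 237 genes), which argues against this as a general cause of calls among them. Knockdown and any other difference between the sets of libraries cannot be told apart, because 0 genotypes had libraries in both sets.

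Lower cell-to-cell variability after irradiation was weighed against capture and cell cycle. Among cells matched on genes detected, 25.01% of the difference was left (-0.102 against -0.41 in as many random cells). More genes captured per irradiated cell could thus account for most of the mean difference. By genotype the matched difference was -0.139 in WT and -0.0662 in the knockdown, against -0.33 and -0.589 over all cells, so more was left in WT. The number of genes detected and the variability come from the same counts, so matching may also remove a real change. Among G1 cells, 9 to 24 per library, 99.08% was left (-0.451 against -0.455). With so few cells this argues only weakly against a shifted mix of phases.

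For the average response the 8 libraries were split into 4 and 4 in all 35 ways. Each fit held genotype as a further term except that of the split by genotype itself. The real split called 60 genes in this fit, against 186 for the average in the fit of 4 groups. Counting it, 2 of the 35 splits called as many, so chance is not excluded by this count. The other was the split by genotype with 1300, from a fit unlike the rest, and it points to the genotype structure of the libraries. The remaining splits, fitted like the real split, called at most 20 genes. The split with 20 also divided the knockdown libraries by treatment. Many of the others were uneven over genotype, so they do not match the real split in power.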

How the results depend on the processing

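No alternative in this part was chosen after the data were seen except the mean of ATM over treatments. No paired analysis was possible because the labels give no replicate numbers that link libraries of different groups. Of 175 calls of named genes, 119 held under every alternative and 0 reversed. Without a filter on low counts the genes called numbered 534 for irradiation in WT, 236 in the knockdown, 580 for the average, 195 for the difference between genotypes and 1044 between irradiated genotypes. DESeq2's Wald test called 585, 177, 558, 159 and 1106 in that order. With an average log2 CPM of at least 5 there were 322 for WT and 45 for the difference. On the mean CPM per cell limma called 122 for the knockdown and 369 for the average. Without cells above 2 times the median total 130 were called in WT and 68 in the knockdown. Fits of the compared groups alone called 33 in WT, 65 in the knockdown and 718 between untreated genotypes; this alternative does not apply to the average or the difference. The cause was not tested in these cases, apart from the number of genes or libraries that the alternative itself changes.

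Leaving out each library gave 89 to 376 genes in WT, 44 to 142 in the knockdown, 137 to 375 for the average, 31 to 128 for the difference, 965 to 1390 between untreated and 308 to 980 between irradiated genotypes, where the lone library left in a group is assumed to vary like the others. The 14 lists that passed for the average became 0 with an estimated correlation, 1 with fry and 11 to 16 without a library. The 11 in WT became 0, 0 and 9 to 12, and the 14 in the knockdown 1, 3 and 11 to 15. The G2/M share ranged from -16.6 to -5.49 points and the variability from -0.526 to -0.393. Across all values and alternatives 5357 were counted as the same. For a gene or a measure per cell this meant the same side of the threshold, with the direction kept where it passed. For a count of genes, lists or clusters it meant a change of at most 1.5 times. Of the others, 395 passed the threshold anew, 139 no longer passed it and 49 counts moved by more than 1.5 times. Depth limits genes of few counts. With 2 libraries per group a 2-fold change was recovered in 56% of simulated cases. These were genes with an average log2 CPM of at least 5, so the share does not cover genes of few counts.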

Other observations

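The ribosome biogenesis list, the ATM contrast over both treatments and the looser rule for counts crossing between barcodes were tests chosen only after the results were seen. Genes that build ribosomes may rise together after irradiation in WT: of 42 such genes 36 were higher, 13 were called and the median log2 change was 0.67, with a camera p of 0.02958 with an estimated correlation, or 0.0887 adjusted over 3 contrasts, so the hypothesis did not pass the adjusted threshold. In the knockdown the median was 0.22 (p = 0.119) and the difference between genotypes -0.51 (p = 0.112, both by camera with an estimated correlation).

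Genes called in both genotypes after irradiation were FAM111B upward (0.0363 expected if independent) and RAB17, CXCL1, CSF1, H1F0 and CLDN4 downward (0.177 expected), and 0 genes were called in opposite directions. Between knockdown and WT, 153 genes were higher and 199 lower with and without irradiation (13.1 and 18.6 expected). BIRC3, CXCL2 and ZC3H12A were higher in untreated and lower in irradiated knockdown, and SLC4A7, AMIGO2 and ACTG1 the reverse. Of the genes irradiation raised in WT, 66 were also higher in the untreated knockdown, and of those it lowered, 63 were lower there, with SOD2 the only gene called in opposite directions. These contrasts share the untreated WT libraries, and simulated counts with no change gave a correlation across genes of 0.495 against 0.568 observed, and a covariance of 0.0397 against 0.164. Genes are not independent replicates.

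Cluster 4 (26 cells), led by SPANXB1, KRT81, AGR2 and SOX4, held 1 to 7 cells of each library. CCL2 was detected in 11 of 43 and 2 of 46 thinned cells of untreated WT and in 8 of 39 and 3 of 46 of irradiated WT. Counts crossing between barcodes were estimated from genes held by a single cell. A minimum of 1000 counts selected 0 or 1 genes per library, so 300 was used instead, which selected 0 to 3 genes per library, with 0.224% to 9.16% of counts outside the top cell. On the first scaling dimension (24.4% of variance) untreated WT libraries lay at 1.90 and 2.12, irradiated WT at 0.80 and 0.55 and knockdown libraries from -1.55 to -1.22.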
